A study of Caenorhabditis elegans with 2 samples.

How the data were processed

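Chromatin immunoprecipitation with sequencing was used to map where the homeodomain protein IRX-1 sits on the genome of Caenorhabditis elegans larvae. Per the labels, the worms (strain OP536) carry a transgene that adds a green fluorescent protein and FLAG tag to the C-terminus of IRX-1, in an unc-119 mutant background, and the tagged protein was pulled down with an antibody against GFP. Whole hermaphrodite L1 larvae were taken 6 hours after synchronization by starvation of bleached animals, and chromatin was sheared by sonication, per the labels. The series holds 1 group of 2 biological replicates, with no second condition, so no difference between conditions could be tested.

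The authors deposited peak lists, not read counts, on the ce11 and ce10 genome builds. Per the file headers of the accompanying notes, each build has a permissive list of peaks and background for each replicate, a permissive list called on the pooled alignments of both replicates, and an optimal list that passed a threshold on the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks repeat between replicates. Each list was derived from alignments together with a control file, per the same notes. The peak caller, the aligner, the IDR cutoff and their versions are not given in the sources used here. Each deposited region carries a peak score from the authors' caller, with no stated formula, and a deposited −log10 q value that saturates at a shared highest value in each list. All peak scores in the text are the authors' own. They were used to describe, rank or filter peaks, to compare median scores within a list, and to correlate the replicate lists. The −log10 q values were used only for an alternative ranking, with ties broken by score.

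No read totals were used, so the sequencing depth of each replicate is unknown, and no interval that depends on depth is given. Shares of peaks or genes have 95% Wilson intervals, which cover counting error only. Where a count is 0, the limit given in the text is instead that of 3 counts of the total, which is somewhat lower than the upper Wilson bound. The replicate 1 list holds exactly 30000 regions on either build. Since the replicate lists differ in length, their overlap was taken among the top 2445 regions of each, the size of the optimal list. The correlation of scores and the replicate ranks of single peaks used any region of a replicate list that holds the optimal summit.

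Summits were set against the Ensembl release 115 annotation and the RefSeq sequence of WBcel235, the assembly that ce11 names. The promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated start of each of 19973 protein-coding genes. Background regions were the 25137 regions of the pooled permissive list that overlap no optimal peak. Coordinates are 1-based on ce11. The ce10 lists were used only for counts and comparisons within that build, and no coordinate was converted.

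Agreement of the replicates was tested with 1000 circular shifts of the replicate 1 peaks along each chromosome (one-sided permutation test, 1 bp of overlap). Shares of peaks or genes were compared with two-sided Fisher's exact tests. Gene lists were tested against all other protein-coding genes, with Benjamini-Hochberg adjustment over 23 lists. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of the members of those lists, 5 microRNA names of the heterochronic pathway, 1 of the epidermis list and 1 of the stress list matched no protein-coding gene symbol. Counts are over gene identifiers, since 97 symbols are carried by more than 1 protein-coding gene. Sequences within 50 bp of each summit were compared with windows of the same width centred 300 bp away on either side, by exact McNemar tests, two-sided. The odds ratio of a 6-mer divides pairs with it at the summit only by pairs with it in the flank only. Pairs were summed over both flanks, with a small constant added. The p of a 6-mer is the larger of those for the left and right flank, and adjustment was over 2080 6-mers. Median scores were compared by permutation (100000 draws, two-sided). Peaks are not independent replicates, and 88 optimal peaks overlap another, so p-values over peaks describe these pooled lists.

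The rule for named genes took 20 protein-coding genes whose windows hold the highest-scoring optimal summits also overlapped in both replicate lists, the 4 members with the highest-scoring summit of each list past an adjusted p of 0.05, irx-1 and unc-119 whatever their values, and each member of the GABA motor neuron list with an optimal summit. A summit in the windows of 2 genes names both.

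Alternatives covered the other genome build, the 1222 optimal peaks with the highest scores, windows and flanks of other sizes, other backgrounds, other definitions of a shared peak, the model with upstream intergenic length, assignment to the nearest gene start, other motif forms, and the top 2445 regions of each replicate alone. A background of only those 7614 genes with a pooled region in their window was added after seeing the data. On simulated data, overlap of 59.5% of 2445 peaks was measured as 61.6%, 99% of 100 gene lists set to 40% occupancy were called, and 0.348% of 287 unchanged lists were called. Only larger lists were set to 40%, which left out the GABA motor neuron list (19 genes) and the heterochronic list (9 genes). Lowered occupancy was not simulated, so the simulation gives no power for small lists or for lists occupied less often. The ACATGT core planted in 5% of 2445 windows ranked 1 among 6-mers, with an adjusted p of 1.48e-09. Those windows were taken away from the summits. At the summits themselves 555 6-mers were higher than in the flanks, so the simulated rank does not carry over to them. Computations used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.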

Results

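The data are peak lists from IRX-1-eGFP chromatin immunoprecipitation in whole L1 larvae, 1 group with 2 biological replicates. IRX-1 is the worm member of the Iroquois homeodomain family, known for its part in the remodelling of GABAergic DD motor neuron synapses. The authors' optimal list holds 2445 peaks on ce11 and 2481 on ce10. It equals the 2445 highest-scoring of the 28191 regions in the pooled permissive list, 8.67% of them, with scores from 81.4 to 1184.9 and a median of 131. The permissive lists hold 30000 regions for replicate 1 and 24949 for replicate 2, and the depth of the libraries is unknown. The merged optimal peaks cover 913.5 kb, and their median width is 410 bp.

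The first comparison asks whether both replicates place IRX-1-eGFP at the same sites. They largely did, and the strongest sites were shared: the promoter peak between F56G4.6 and wbp-4 ranked 6 in replicate 1 and 1 in replicate 2, that at the ribosomal protein gene rpl-3 ranked 2 and 4, and that at rpl-20 ranked 3 and 6. Of the top 2445 regions of replicate 1, 1860 (76.1%) overlapped the top 2445 of replicate 2. Shifted peaks gave a mean of 1.83% and at most 2.82% (permutation p = 0.001, the smallest that 1000 shifts can give). Of the optimal peaks, 1842 (75.3%) were overlapped by the top 2445 of both replicates. Across 2426 optimal peaks whose summit lies inside a region of both replicate lists, Spearman's rho of the scores was 0.743 (95% bootstrap interval 0.718 to 0.765), a correlation across peaks, which are not independent replicates.

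**Figure D1:**
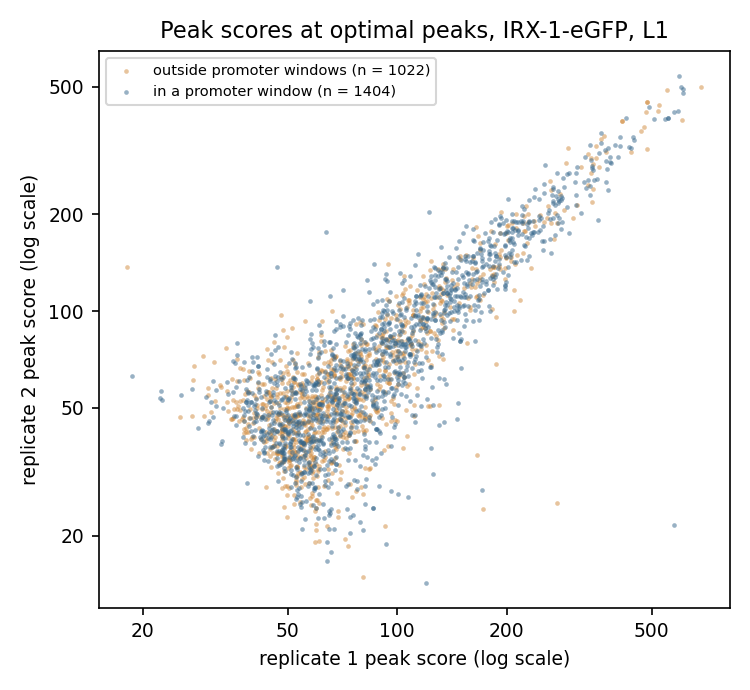
Authors' peak scores of replicate 1 (x axis) and replicate 2 (y axis), log scales, at the 2426 optimal peaks whose summit is inside a region of both replicate lists, coloured by whether it lies in a promoter window. High-scoring peaks lie along a narrow band and low-scoring ones spread more widely, with a rho of 0.743 over all.

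The location of the peaks shows in which parts of genes the IRX-1-eGFP signal lay. Most summits lay in a promoter window, 1000 bp upstream to 200 bp downstream of a gene start. For protein-coding genes, 1414 of 2445 (57.8%, interval 55.9 to 59.8%) did, against 24.4% of background regions. In the replicates' own top lists the share was 56.3% ± 0.347 (SD, n = 2). Intergenic sequence held 73.01% of optimal summits and 44.3% of background summits. Coding exons held 17 optimal summits (0.695%, against 13.7%), introns 21.4% (against 36.1%), 3' UTRs 1.19% (against 3.52%) and 5' UTRs 3.56% (against 2.15%). The promoter difference had an odds ratio of 4.26 (Fisher's exact test, two-sided, p = 7.94e-244). Random positions had a promoter share of 21.6%, near that of background regions. The difference therefore cannot tell occupancy by IRX-1 from promoter signal shared by many immunoprecipitations. The median distance from a summit to the nearest protein-coding gene start was 458 bp for optimal peaks and 1656 bp for background regions.

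**Figure D2:**
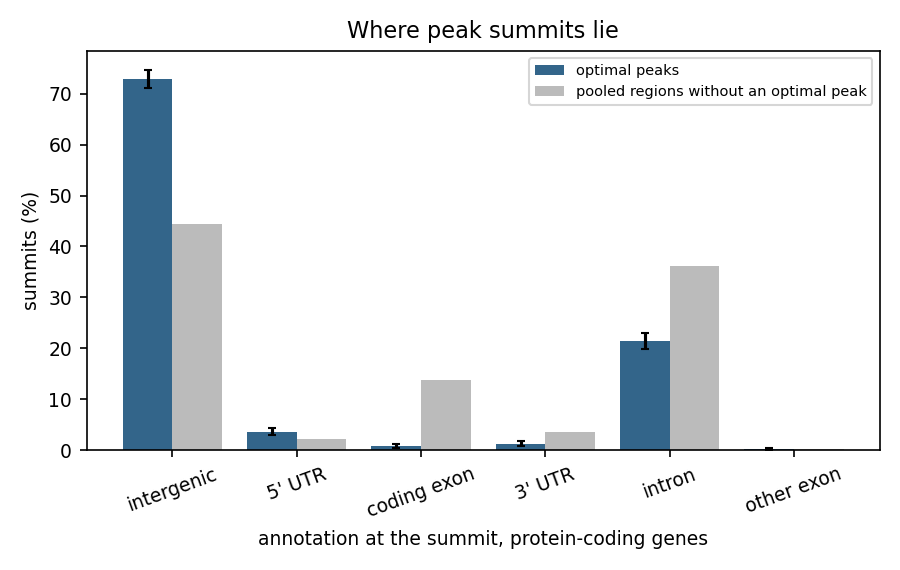
Percent of summits (y axis) in each annotation class of protein-coding genes (x axis), for 2445 optimal peaks and 25137 background regions. Bars start at 0, and error bars on the optimal peaks are 95% Wilson intervals. Intergenic sequence holds 73.01% of the optimal summits and coding exons 0.695%.

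Promoter peaks had the higher median score. It was 144 and that of the other optimal peaks 119.1, a difference of 24.9 (permutation p = 1e-05, two-sided, the smallest that 100000 draws can give). The difference had the same sign in each replicate list, at 15.02 for replicate 1 and 12.1 for replicate 2, whose score scales are not comparable with the pooled list. The promoter share was 64.1% among the 1222 highest-scoring peaks. Of the 20 highest-scoring peaks 11 lay in a promoter window, and 6 of the other 9 lay on X.

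The genes with the strongest promoter peaks include housekeeping genes and pairs of divergent neighbours. The highest-scoring promoter peak (chromosome I, 11374295 to 11374592, score 1139) is intergenic, between F56G4.6 and wbp-4 and 181 bp upstream of the latter. The next (chromosome III, 7520711 to 7520987, score 1101) lies at the start of cux-7, 163 bp from C07H6.2 and 617 bp from lig-4, which encodes a DNA ligase. The peak of rpl-3 (chromosome III, 3867427 to 3867719, score 1093) is intergenic and 294 bp upstream of the gene. The peak shared by rpl-20 and Y17G9B.5 (chromosome IV, 4749926 to 4750214, score 1087) lies 290 bp and 172 bp upstream of them. The summit that names H41C03.3 (chromosome II, position 5844830, score 1011) is next to sls-2.1, and that of egg-5 (chromosome I, position 4172176, score 996.8) is next to sls-2.4. Both sls-2 genes encode spliced leader RNAs and lie nearer to the summit than the protein-coding genes do. Peaks of tasp-1 and K01G5.10 (score 933.6), cdc-48.1, a AAA ATPase of protein quality control (919.6), rpl-35 (898.5) and the mitochondrial chaperonin gene hsp-60 with Y22D7AL.10 (792.1) follow. The rule also named nspc-17 on X (952.2), W04C9.4 (826.5), C47E8.4 (796.8) and F01D4.5 (762.7). The summit of C47E8.4 lies 269 bp upstream of its start, in an intron of another protein-coding gene.

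The tagged gene itself carried a peak. The irx-1 gene (WBGene00007984, chromosome I, 9536465 to 9540966, minus strand) had an optimal summit 301 bp upstream of its start, in intergenic sequence (9541062 to 9541471, score 321.7), which ranked 280 in the pooled list, 307 in replicate 1 and 278 in replicate 2. Within 20 kb of its start lay 10 optimal peaks, 7 of them inside the upstream neighbour swah-1, where the highest (9546354 to 9546464) scored 369.3. The other autosomal windows of 40 kb, placed every 20 kb so that neighbours overlap, held a median of 1 and at most 9. With overlapping peaks joined, the window of irx-1 held 8, a count that 3 of 4116 other windows reached. The unc-119 gene (WBGene00006843, chromosome III, 10902641 to 10908935), mutated in this strain, had 0 optimal summits in its window and 0 within 20 kb of its start. Regions below the threshold numbered 25 around unc-119, at percentile 99.5 of those windows, and 13 around irx-1, at percentile 70.6.

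**Figure D3:**
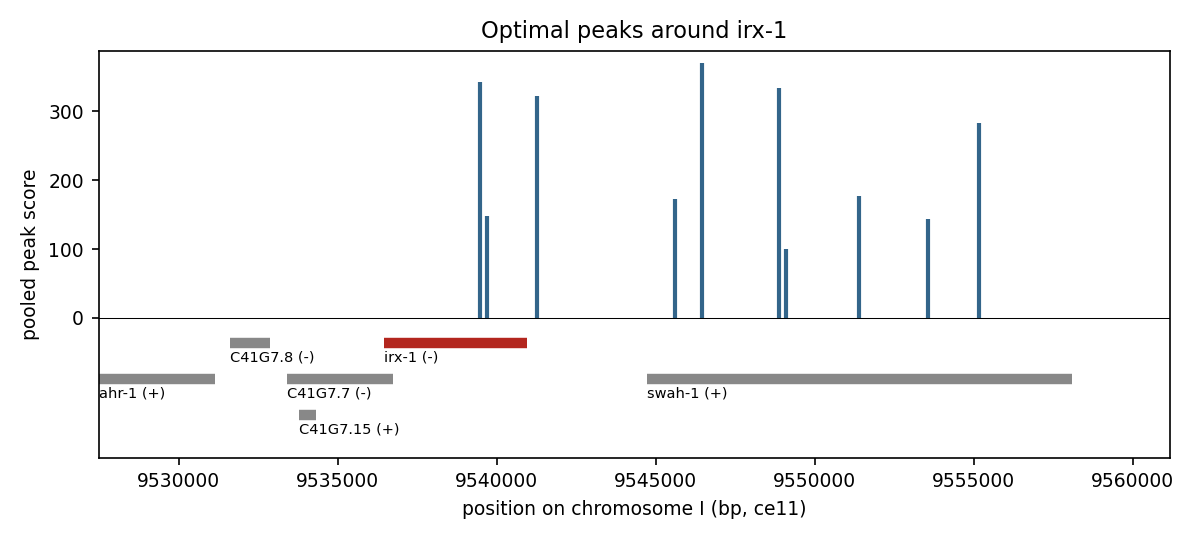
Pooled peak score (y axis) of the 10 optimal peaks within 20 kb of the irx-1 start, at their summit positions on chromosome I in ce11 (x axis), with protein-coding genes and their strands drawn below. The peaks lie in and upstream of irx-1 and over swah-1, with scores up to 369.3.

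Gene groups were compared to see which kinds of promoters were occupied. Cytosolic ribosomal protein genes stood out: 58 of 80 (72.5%, interval 61.9 to 81.1%) had an optimal summit in the promoter window, against 9.35% of other protein-coding genes, an odds ratio of 25.6 (exact adjusted p = 1.58e-40). The highest scores among them belonged to rpl-3, rpl-20, rpl-35 and rpl-15 (1093, 1087, 898.5 and 739.2). In the replicates' own top lists 73.1% ± 2.65 of these genes were occupied (SD, n = 2). The odds ratio was 11.8 over genes with a pooled region in their window and 6.33 by nearest gene start, where 42.5% were occupied. Heterochronic genes, which time larval cell fates, were occupied in 4 of 9 cases (44.4%, interval 18.9 to 73.3%, odds ratio 7.55, exact adjusted p = 0.0275). These were lin-66 (score 149.7), lin-14 (132.5), lin-46 (127.6) and lin-28 (91.7). The heterochronic call was lost without replicate 2 (odds ratio 4.88, exact adjusted p = 0.130), in the narrower promoter window (3.44, adjusted p = 0.310) and among the 1222 highest-scoring peaks (4.83, adjusted p = 0.222). Over genes with a pooled region in their window it was lost at a higher odds ratio, 11.9 (exact adjusted p = 0.0587), with 4 of 5 such genes occupied. The odds ratio was 14.5 in the wider window and 29.7 by nearest gene start, where the list passed.

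Sensory, detoxification, neuropeptide and germline genes were occupied less often than other genes. Of 1310 chemoreceptor genes, 10 (0.763%) had an optimal summit, with an odds ratio of 0.0676 (exact adjusted p = 2.67e-43). The highest-scoring were srh-16 (353.6), sri-5 (282.6), sre-23 (150.1) and srh-89 (120.9). The odds ratio of chemoreceptor genes was 0.112 over genes with a pooled region in their window and 0.0361 among the 1222 highest-scoring peaks. Of 199 detoxification genes, 3 were occupied, namely the glutathione S-transferase genes gst-27 (169.3) and gst-5 (83.3) and the cytochrome P450 gene cyp-13A2 (97.2), with an odds ratio of 0.143 (exact adjusted p = 3.97e-05). Without replicate 1 the count was 1 and the odds ratio 0.0491, and by nearest gene start they were 6 and 0.261. Of 140 neuropeptide genes, ins-39 (436.4) and nlp-4 (131.5) were occupied, with an odds ratio of 0.136 (exact adjusted p = 0.000822), and by nearest gene start 6 were, with an odds ratio of 0.376. None of 59 germline genes was occupied, a count of 0 that allows up to 5.08% (exact adjusted p = 0.0274). The summits at sre-23 and gst-27 lie within 200 bp of the snoRNA genes ZK265.10 and Y53F4B.48. The germline count stayed at 0 in 8 of 8 alternatives, but its call was lost in the narrower window (exact adjusted p = 0.104), among the 1222 highest-scoring peaks (adjusted p = 0.222) and over genes with a pooled region in their window (adjusted p = 0.637), and the neuropeptide call among the 1222 highest-scoring peaks (adjusted p = 0.0970).

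The remaining 17 lists did not pass the test. GABA motor neuron and DD remodelling genes were occupied in 2 of 19 cases (10.5%, exact adjusted p = 0.899), irx-1 itself and lin-14, whose summit (chromosome X, 11465105 to 11465514, score 132.5) lies 250 bp upstream in intergenic sequence. Some other members had pooled regions only below the optimal threshold, and were named after their values were seen. They included the sodium channel gene unc-8 (pooled score 41.1), the GABA receptor gene unc-49 (69.0) and the GABA transporter gene snf-11 (60.5). The windows of unc-49 and snf-11 held a summit in both replicate lists, but that of unc-8 held none in replicate 2. The remaining such members were unc-25, with no summit in replicate 1, and oig-1, with none in either replicate. Pan-neuronal and synaptic vesicle genes were occupied in 6 of 28 cases (exact adjusted p = 0.133). That list passed with the top regions of replicate 1 alone (exact adjusted p = 0.0473), with those of replicate 2 alone (adjusted p = 0.00300), in the wider promoter window (adjusted p = 0.000964) and by nearest gene start (adjusted p = 1.67e-07). It did not pass among the 1222 highest-scoring peaks (exact adjusted p = 0.471), in the narrower window (adjusted p = 0.171), with upstream length in the model, or over genes with a pooled region, where the odds ratio fell from 2.57 to 1.11 (adjusted p = 0.935). Heat shock and stress genes were occupied in 6 of 33 cases (exact adjusted p = 0.265) and passed with replicate 2 alone (adjusted p = 0.00916). Occupied genes numbered 4 of 98 among homeobox factors (exact adjusted p = 0.189), 4 of 39 among bHLH factors (0.904), 20 of 274 among nuclear hormone receptors (0.381), and 0 of 26 among T-box and SOX factors (0.326), which allows up to 11.5%. They numbered 1 of 19 for cholinergic neurons (exact adjusted p = 1), 2 of 32 for axon guidance (0.904), 4 of 25 for Wnt signalling (0.452) and 2 of 76 for DEG/ENaC and potassium channels (0.104). They numbered 3 of 36 for body wall muscle (exact adjusted p = 1), 1 of 30 for epidermis and seam cells (0.514), 10 of 177 for collagens (0.187), 1 of 28 for intestine (0.696) and 7 of 72 for histones (1). Pharynx genes were occupied in 0 of 21 cases (exact adjusted p = 0.421), which allows up to 14.3%.

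**Figure D4:**
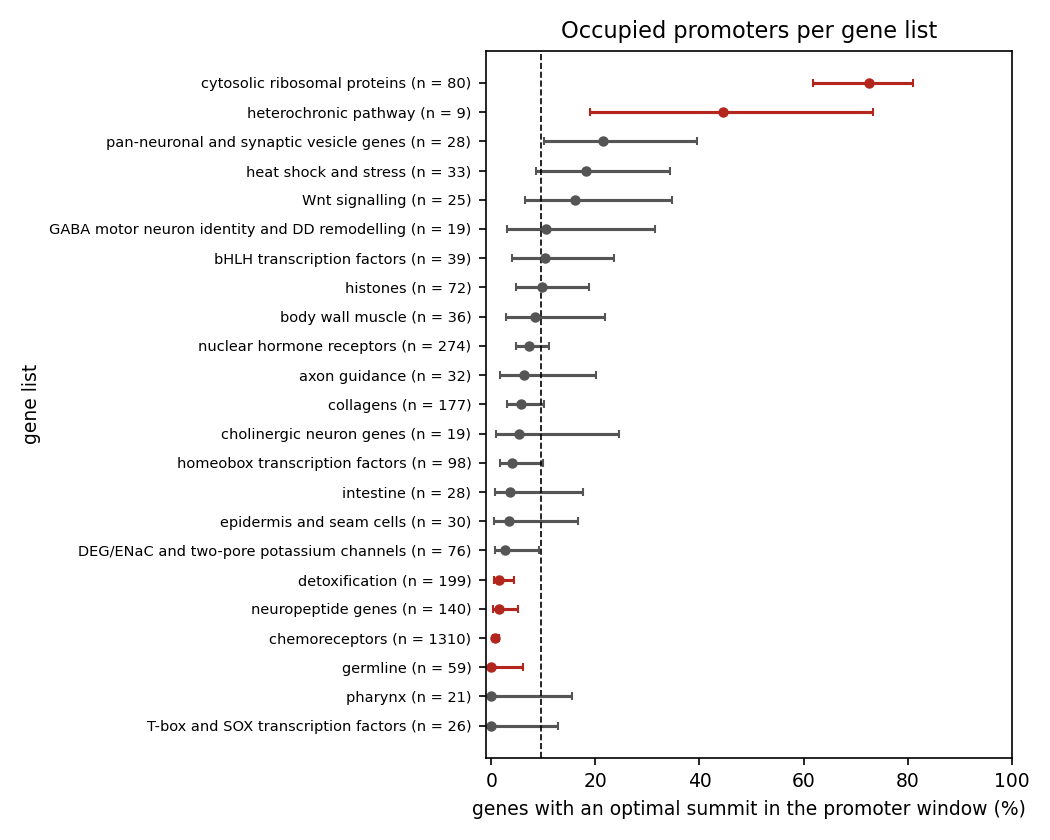
Percent of the genes of each list (y axis, n genes in brackets) with an optimal summit in the promoter window (x axis). Points are shares, bars are 95% Wilson intervals, red marks lists with an adjusted p under 0.05, and the dashed line is the share over all protein-coding genes, 9.60%. Ribosomal protein genes lie at 72.5% and chemoreceptor genes at 0.763%.

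The X chromosome, which carries its own regulation in worms, was compared with the autosomes. X held 461 optimal peaks (18.9%, interval 17.4 to 20.5%) and 19.2% of background regions, a difference that was not detected (odds ratio 0.978, Fisher's exact test, two-sided, p = 0.706). In the replicates' own top lists the share was 18.7% ± 0.231 (SD, n = 2). Among the 1222 highest-scoring peaks the X share was lower, at 16.7% (exact p = 0.0305). Peaks per megabase ranged from 17.9 on chromosome V to 30.3 on chromosome III.

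The sequence at the summits was searched for the ACATGT core known from mouse Iroquois proteins. Of 2445 summits, 82 (3.35%, interval 2.71 to 4.14%) had the core within 50 bp, against 2.25% of left flanks (exact McNemar p = 0.0227) and 2.74% of right flanks (exact McNemar p = 0.242), so the difference did not hold on both sides. ACATGT ranked 733 among 2080 6-mers by odds ratio (1.36, exact adjusted p = 0.365), and 37 among the 492 6-mers with as many G and C bases. In all, 555 6-mers were higher at summits and 435 lower. Those with the highest odds ratios included CGCGCG (5.73% of summits, odds ratio 9.16), ACGCAG (15.9%, 8.82) and GACGCA (15.8%, 8.65), and GAGAGA was present at 26.5% of summits against 7.20% and 6.13% of flanks. CTGGAA was the lowest (2.58% of summits, odds ratio 0.250). GC content averaged 45.5% at summits and 35.6% and 35.4% in the flanks, and it was 35.0% at background summits. The shorter form TTACA or TGTAA was rarer at summits (12.1%) than in the flanks (20.6% and 21.5%, larger exact McNemar p = 9.55e-16).

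**Figure D5:**
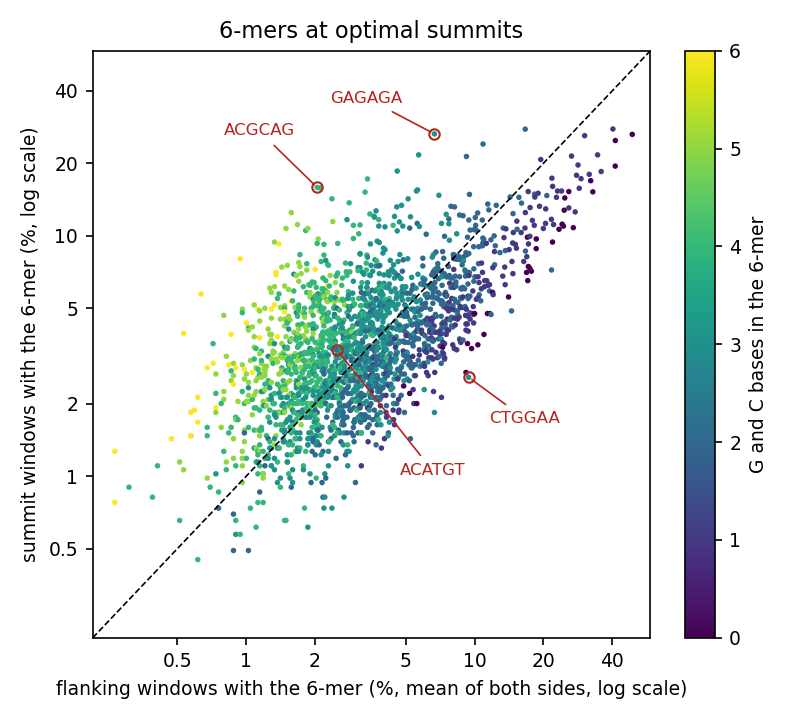
Percent of summit windows (y axis) and of flanking windows (x axis, mean of both sides) that hold each of 2080 6-mers, log scales, coloured by the number of G and C bases, with a dashed line of equality. ACATGT lies near the line at 3.35% of summits, ACGCAG above it at 15.9% and CTGGAA below it at 2.58%.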

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

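Of 53 alternative values of the main results, 42 kept their direction and their side of the threshold or their range. The replicate overlap (5 alternatives, 69.9 to 82.5%), the promoter share (7 alternatives, 48.8 to 67.0%) and the higher score of promoter peaks (5 alternatives) did so in each case. Spearman's rho rose to 0.814 among the 1222 highest-scoring peaks, and Pearson's r of log2 scores was 0.823. The X share lay further below background among those 1222 peaks, at 16.7%. The X share of 18.9% lay above, not below, the comparator when set against the share of genome length (17.7%, exact p = 0.124) or against the lowest-ranked pooled regions (18.6%, p = 0.855), and neither difference passed the test. Lists occupied more often numbered 2, and 1 with the 1222 highest-scoring peaks, 1 with the window of 500 bp upstream to 100 bp downstream, and 1 over genes with a pooled region in the window, a background chosen after seeing the data. Leaving out either replicate gave 2 to 4 lists. The tally of 42 scored the number of lists and not which ones passed. Without replicate 2 the number stayed at 2, but pan-neuronal genes passed in place of heterochronic genes. Lists occupied less often numbered 4, and 2 with the 1222 highest-scoring peaks. There the neuropeptide count stayed at 2 of 140, and its odds ratio moved from 0.136 to 0.243. Over genes with a pooled region, nuclear hormone receptors also passed as lower (exact adjusted p = 0.0450). The motif form TTACA or TGTAA was lower at summits (12.1%) instead of higher. The causes of these changes were not tested. The calls for ribosomal protein, chemoreceptor and detoxification genes held under 8 of 8 alternatives each, that for neuropeptide genes under 7, for germline genes under 5 and for heterochronic genes under 4. No paired analysis was possible because the series holds 1 group. The depth of the libraries is unknown, so weak sites missed for lack of reads cannot be separated from unoccupied ones.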

Other observations

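The comparisons of small RNA genes, growth-related gene groups, chromosomes and the strongest X peaks, and the tests of transgene copies, of gene density around irx-1, of the ACATGT core at ribosomal protein and small RNA genes, of uptake at tRNA genes and of GCGCAGGG, were chosen only after the results were seen. Peaks also lay near tRNA, snoRNA and snRNA genes, while for microRNA genes no difference was detected (0.368% of optimal and 0.203% of background summits, exact adjusted p = 0.107). Summits within 200 bp of a tRNA gene made up 5.07% of optimal peaks (124 of 2445) and 0.696% of background regions (exact adjusted p = 1.59e-51), and 128 of 612 tRNA genes had such a summit. For snoRNA genes the shares were 3.19% and 0.251% (exact adjusted p = 2.92e-44), and for snRNA genes 1.06% and 0.0637% (adjusted p = 2.74e-17). The spliced leader genes sls-2.1, sls-2.4 and sls-2.2 lay at pooled ranks 7, 8 and 18. For piRNA genes, which crowd chromosome IV, the share was lower: 0.818% of optimal summits and 4.24% of background summits lay within 200 bp of them (exact adjusted p = 3.06e-22). The shares were higher for lincRNA genes (0.941% against 0.418%) and lower for pseudogenes (0.777% against 1.79%). Both replicates' top lists gave tRNA shares near the pooled value, 4.79% ± 0.116 (SD, n = 2).

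Other growth-related gene groups had occupied promoters more often than the remaining genes (Fisher's exact tests, two-sided, adjusted over 7 lists). Translation initiation factor genes were occupied in 15 of 33 cases (odds ratio 7.90, exact adjusted p = 6.96e-07), led by eif-3.B (score 620.0) and iff-2 (540.9). Cytochrome c oxidase genes were occupied in 7 of 15 cases (exact adjusted p = 0.000417), led by cox-5A (750.9), and proteasome genes in 12 of 33 (adjusted p = 0.000107), led by rpn-3 (398.7). The summit of rpn-3 also lies in the window of hsp-110. Mitochondrial ribosomal protein genes were occupied in 17 of 66 cases (exact adjusted p = 0.000281), CCT chaperonin genes in 4 of 8 (adjusted p = 0.00604), vacuolar ATPase genes in 5 of 20 (adjusted p = 0.0370) and aminoacyl-tRNA synthetase genes in 7 of 32 (adjusted p = 0.0343). Assignment to the nearest gene start and the background of genes with a pooled region were not applied to these 7 lists. By chromosome, I, II and III held larger shares of optimal peaks than of background (18.1% against 15.5%, 15.1% against 12.2% and 17.1% against 15.4%), and IV and V smaller ones (15.6% against 18.9% and 15.3% against 18.8%), with an exact adjusted p of 0.0424 for III and of at most 0.00150 for the others. Against its 15.2% of genome length the share of chromosome II was not larger.

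The 10 optimal peaks around irx-1 compare with at most 9 in 4116 other autosomal windows of 40 kb, and with overlapping peaks joined the count is 8, which 3 of those windows reach. Neighbouring windows overlap, so these counts and percentiles are not over independent stretches. Gene density is argued against, since the 7 gene starts in the window lie at percentile 34.2. Extra copies of the locus in the inserted transgene could raise the background there, unless the control, whose strain is not given in the sources used here, carries them too: the median score of regions below the threshold lay at percentile 40.1 of the windows in the pooled list, 47.7 in replicate 1 and 94.0 in replicate 2. With 13, 11 and 13 such regions the bootstrap intervals run from 5.24 to 99.2, from 9.64 to 94.5 and from 2.66 to 99.6, too wide to decide, so extra copies and occupancy of the native locus cannot be told apart. Since the design holds 1 group, no biological explanation of this cluster was tested.

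Of 282 optimal summits at ribosomal protein promoters or small RNA genes, 15 (5.32%, interval 3.25 to 8.59%) had ACATGT, 0 of 56 at the former and 15 of 227 at the latter, against 3.10% of other summits (exact p = 0.0754). Recognition of that core at most of these peaks is argued against. The 82 of all 2445 summits with the core had already settled this, since they are too few to make up 50% of the 282. Another motif of IRX-1 stays open. GC content at the summit alone is argued against for the promoter share only. For ribosomal protein genes only the GC content of the whole promoter window is argued against. Background regions weighted to the GC content of the optimal summits had a promoter share of 26.4% (bootstrap interval 25.5 to 27.4%) against 57.8%. Ribosomal protein genes kept an odds ratio of 22.2 (interval 13.5 to 36.6) with the GC content of the whole promoter window in the model. Its median was 37.0% for these genes and 34.9% for others. The model does not cover GC content within 50 bp of their summits, which was not tested. GC content was not tested for the small RNA genes, which hold 227 of the 282 summits. Uptake of these sites in common by many factors at highly transcribed genes cannot be told apart from occupancy by IRX-1, because the odds ratio of 7.62 for tRNA genes is part of the pattern and peaks of other factors were not analysed here.

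Outside promoter windows 14 of 264 X peaks and 19 of 767 autosomal ones were among the top 100 (odds ratio 2.20, exact p = 0.0400; in replicate 1 alone 2.04, p = 0.0624, and in replicate 2 alone 2.56, p = 0.0182), but inside them 4 of 197 and 63 of 1217 were (0.380, p = 0.0680), and over all peaks 18 of 461 and 82 of 1984 (0.942, p = 0.897). Small RNA genes within 200 bp of the X summits are argued against, since all 14 stayed without peaks near such genes (14 of 209, odds ratio 2.72, exact p = 0.00885). Among X peaks only lower-ranked ones were left out, so the rise from 2.20 is no further evidence. The X peak at rank 19 ends at 8036679, next to a tRNA gene at 8036685 to 8036757, though its summit lies more than 200 bp away. GCGCAGGG, part of the motif known from sites that recruit the dosage compensation complex to X, was in 9 of these 14 peaks and in 9 of the other 250 X peaks outside promoter windows (odds ratio 48.2, interval 11.3 to 214, exact p = 5.53e-09). Outside promoter windows it was in 0.652% of 767 autosomal optimal peaks and in 0.208% of 3837 X background regions. The highest-scoring peak of the whole list (chromosome X, 11093977 to 11094412, score 1184.9) holds it. Signal at dosage compensation recruitment sites is a candidate explanation that was both found and tested on these data, and whether it reflects IRX-1 or uptake shared by many immunoprecipitations stays open.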
